A study of Homo sapiens with 6 samples.

How the data were processed

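Transcript levels were measured by RNA sequencing of polyA-selected RNA from HCT116, a human colorectal carcinoma cell line of epithelial morphology. Directional paired-end libraries were made from 3 samples labelled siMTA1 and 3 control samples, per the labels' protocols. The submitters' processing notes name cutadapt, TopHat2 and edgeR and the genome build GRCh38, without versions or roles. How fragments were counted, whether strand was used in counting, and which annotation release and gene lengths entered the values are not given in the sources used here. The authors deposited 1 table of FPKM, fragments scaled to gene length and to the mapped total of the library, for 36651 genes in 6 libraries, printed to 2 decimals. No counts were used here. Reads from overlapping genes, antisense partners and near-identical copies could have been shared or split in the authors' values, so levels of such genes are uncertain.

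Each column was assigned to a sample by its name. The treated samples carry siMTA in their descriptions and in the design text, whereas their titles read CrMTA1, an abbreviation that the labels do not explain. Whether MTA1 was lowered by RNA interference or altered in the genome of a selected line is therefore uncertain, and siMTA1 is used as the name of the group. The control samples are called control in the descriptions and wild type in the titles. The nature of the control, such as a non-targeting RNA, is not given in the sources used here. Nothing in the labels says that replicates came from separate cultures.

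FPKM values carry no depth of their own, but the low values of short genes fell on regular steps. In genes shorter than 150 bases, the depth was taken as the value at which most of the lowest FPKM values equalled 1 fragment, within a tolerance of 0.04. The implied depth was 42900000, 56700000 and 65400000 fragments for control libraries 1, 2 and 3 and 57200000, 66700000 and 61100000 fragments for siMTA1 libraries 1, 2 and 3. Between 94.9% and 97.2% of the low values of these genes were then whole within 0.05 of a unit beyond the rounding of the table. These depths assume that 1 step is 1 fragment and that the gene lengths of GENCODE 29 apply. The FPKM of a library summed to between 391356 and 403165, and 3525 genes were listed at 0 in all 6 libraries.

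Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 12141. The test was run in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), with an empirical Bayes fit with an intensity trend, two-sided, siMTA1 against control without covariates. P-values were adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called changed. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. A positive log2 fold change means a higher level with siMTA1. For MTA1 alone, an exact two-sided permutation test of the 6 values was added. The design planned a count-based test in case the table held counts, and the test for FPKM was used because it does not.

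Before the data were examined, 29 gene lists were fixed, covering complexes, pathways and markers of other cell types. Of their 871 entries, 837 were found in the table, and the 22 lists with at least 5 tested members were tested with camera, a competitive set test of limma, at a preset correlation between genes of 0.01. Adjusted p-values of lists are over these 22. Beside it stand camera with an estimated correlation and fry, a rotation test. The genes to be named were also fixed by rule. They were MTA1, the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap and whose mean reached 5 FPKM in the higher group, all NuRD subunits, and the members with the smallest adjusted p of each list. That was up to 4 for a list past the set test and up to 2 for another list. Coordinates are those of GENCODE 29 on GRCh38, in which 35749 of the 36651 gene identifiers were found. Exon length and GC content for the bias check came from the same release.

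The test was tried on simulated data of 12141 genes with 50 genes changed at each of several sizes. It recovered 50% of genes changed by 0.3 on the log2 scale, 82% of those changed by 0.6, 94% of those changed by 1 and 100% of those changed by 1.5, and 2.4% of its calls were false. A further set of 30 genes was shifted by a smaller size. Noise was drawn independently for each gene, and a far smaller share of genes was changed than was called in the data. The recovered and false shares therefore describe the simulation and need not hold for the data. The alternatives tried were other pseudocounts, other filters on low values, other scalings, other settings of limma, the replicate number as a block, and each library left out in turn. The implied depths and the figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and the test results were tabulated in R.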

Results

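Gene expression was compared between HCT116 colorectal carcinoma cells labelled siMTA1 (3 libraries) and control cells of the same line (3 libraries). MTA1 is a subunit of NuRD, a complex that remodels nucleosomes and removes acetyl groups from histones. The comparison asks which transcripts differ in level where MTA1 is lowered. Splicing, which the study's title also names, was not analysed here. The depth implied by the steps of the low values was 42900000 to 65400000 fragments in the control libraries and 57200000 to 66700000 fragments in the siMTA1 libraries. Across the 12141 tested genes, libraries of the same group correlated with Pearson's r of 0.994 to 0.997 and libraries of different groups with r of 0.988 to 0.992, over genes, which are not independent replicates. The first principal component held 55.8% of the variance and separated the groups. Because the labels do not say that replicates were separate cultures, p-values measure only the spread between these samples, which may be technical.

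The level of MTA1 was lower in every siMTA1 library than in any control library. MTA1 (ENSG00000182979.17) lies on chromosome 14 from 105419820 to 105470729 on the plus strand of GRCh38. It stood at 65.90, 67.61 and 66.74 FPKM in control libraries 1, 2 and 3 and at 44.55, 43.98 and 47.97 FPKM in siMTA1 libraries 1, 2 and 3. Mean levels were 66.75 ± 0.855 FPKM (SD, n = 3) and 45.5 ± 2.16 FPKM (SD, n = 3), so that 68.2% of the control level remained. On the log2 scale MTA1 differed by −0.54 (SE 0.06, limma adjusted p = 0.000376). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow.

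Of the 15 NuRD subunits tested, 3 passed the threshold and all 3 were lower with siMTA1, the same number when adjusted over the list alone. MTA1 itself is among these 3, and 18.2% of all tested genes passed, with 1463 of 12141 lower. Besides MTA1 these were CHD5, a remodelling ATPase, with 1.74 ± 0.13 FPKM in control and 1.30 ± 0.07 FPKM with siMTA1 (SD, n = 3 each), and MBD2, a methyl-CpG binding protein, with 17.8 ± 0.57 and 15.5 ± 0.45 FPKM. The log2 fold change was −0.25 for CHD5 (adjusted p = 0.0340) and −0.19 for MBD2 (adjusted p = 0.0403). Both calls were near the threshold. For CHD5 the adjusted p was 0.0515, 0.126 and 0.0559 without control library 1, 2 or 3, and 0.0914, 0.0912 and 0.0510 without siMTA1 library 1, 2 or 3. For MBD2 it was 0.0825 and 0.139 without control library 1 or 2, and 0.0816, 0.127 and 0.0663 without siMTA1 library 1, 2 or 3. Both calls also ended with no filter on low values (adjusted p = 0.131 for CHD5 and 0.0781 for MBD2), under quantile normalization (0.0639 and 0.0895), upper-quartile scaling (0.0547 and 0.0909) and median centring, chosen after the data were seen (0.0841 and 0.120). The MBD2 call ended as well under TPM (adjusted p = 0.0598) and where a mean of 0.1 FPKM was required (adjusted p = 0.0534). The paralogs MTA2 (log2 fold change −0.17, SE 0.07, adjusted p = 0.113) and MTA3 (−0.10, SE 0.07, adjusted p = 0.341) did not pass. Neither did the deacetylase genes HDAC1 (0.16, SE 0.06, adjusted p = 0.0855) and HDAC2 (0.00, SE 0.07, adjusted p = 0.977) or the ATPase gene CHD4 (0.01, SE 0.06, adjusted p = 0.950). HDAC1 passed under upper-quartile scaling (adjusted p = 0.0454), with array weights (adjusted p = 0.0261) and, among alternatives chosen after the data were seen, with the length and GC trend removed (adjusted p = 0.0447) and with median centring (adjusted p = 0.0371). MTA2 passed with array weights (adjusted p = 0.0278) and with that trend removed (adjusted p = 0.0242). With the replicate number as a block, MTA2 (adjusted p = 0.0312) and HDAC1 (adjusted p = 0.0371) passed as well. NuRD as a list gave a camera adjusted p of 0.973.

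**Figure D1:**
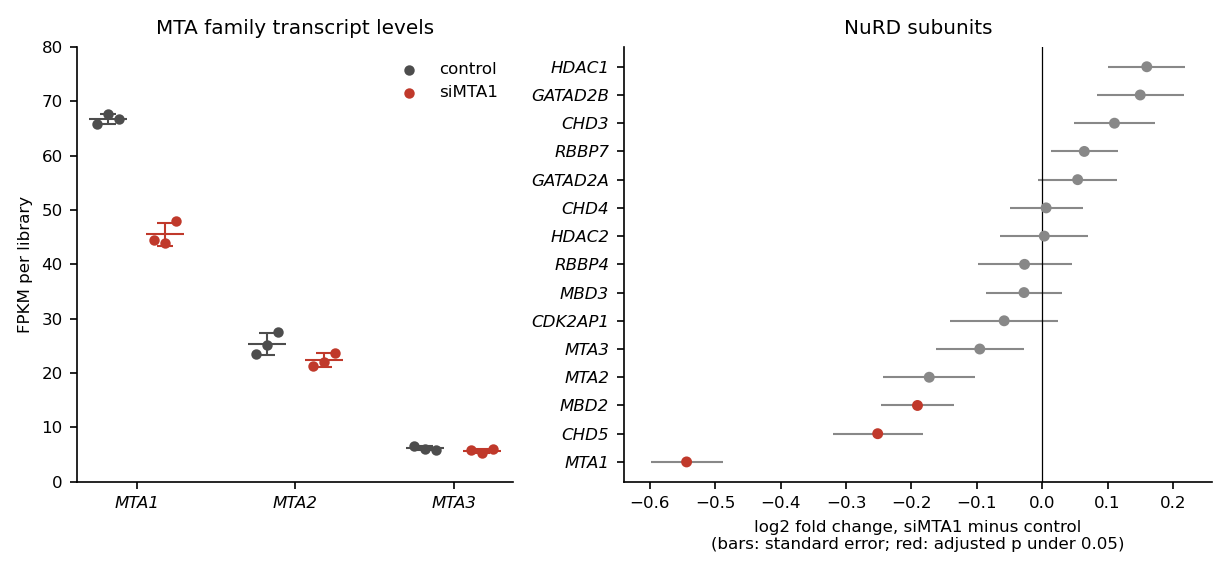
Left, FPKM of MTA1, MTA2 and MTA3 in each library (dots) with the mean and SD of each group of 3; right, log2 fold change (siMTA1 minus control) of the 15 NuRD subunits with standard errors, in red where the adjusted p is under 0.05. MTA1 has the lowest value of the subunits at −0.54, and its 3 siMTA1 libraries lie between 43.98 and 47.97 FPKM, below all 3 controls.

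With siMTA1, 744 genes were higher and 1463 lower, together 2207 or 18.2% of the genes tested (limma, adjusted p under 0.05). Most of these differences were small: 94.1% were under 1.5-fold, and 23 genes changed at least 2-fold, 14 higher and 9 lower. The 3 values of each group did not overlap in 39.1% of tested genes, where chance gives 10%. The balance between higher and lower genes depended on the scaling. Quantile normalization gave 1011 higher and 895 lower, upper-quartile scaling 1000 and 939, and median centring, chosen after the data were seen, 1128 and 802. The number of changed genes was 1046 without control library 2 and 1066 without siMTA1 library 2.

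Among changed genes that reached 5 FPKM, the gene with the largest rise on the log2(FPKM + 1) scale was ANKRD37, a target of hypoxia-inducible factors, at 5.14 ± 1.48 FPKM in control and 32.8 ± 4.80 FPKM with siMTA1 (log2 fold change 2.48, SE 0.15, adjusted p = 1.71e-05). VGF, a precursor of secreted peptides known from neurons and endocrine cells, stood at 18.1 ± 0.16 and 78.9 ± 3.63 FPKM (log2 fold change 2.06). The keratin gene KRT13 was at 0.57 ± 0.11 FPKM in control and 7.21 ± 0.80 FPKM with siMTA1, 12.7-fold as a ratio of mean FPKM against 6.38-fold for ANKRD37. ANGPTL4, whose product inhibits lipoprotein lipase, was at 5.86 ± 0.76 and 26.4 ± 4.02 FPKM, and the water and glycerol channel gene AQP3 at 8.04 ± 0.89 and 29.8 ± 2.66 FPKM. The other large rises were DHRS2, NDRG1, the transcription factor gene EGR1, the signalling protein gene BMP4, the monoamine oxidase gene MAOB, the peptidase gene DPP4, and CTD-2287O16.3, a gene known by a clone name only. Their log2 fold changes lay between 0.85 for DPP4 and 1.33 for DHRS2. All errors are SD with n = 3.

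LCN2, which codes for the iron-scavenging protein lipocalin, showed the largest fall on that scale, from 77.0 ± 5.58 FPKM in control to 17.6 ± 0.92 FPKM with siMTA1 (log2 fold change −2.07, SE 0.07, adjusted p = 3.11e-07). The neutrophil chemokine gene CXCL1 was at 12.3 ± 2.20 and 3.34 ± 0.47 FPKM (log2 fold change −1.61). Urokinase (PLAU) was at 141.1 ± 10.2 and 61.1 ± 3.02 FPKM, and tissue factor (F3), the initiator of coagulation, at 63.7 ± 4.64 and 30.2 ± 1.96 FPKM. MALT1, a protease of NF-kB signalling, was at 20.01 ± 1.05 and 8.94 ± 0.56 FPKM. The kinase gene PLK2 (log2 fold change −1.02), the death receptor gene FAS (−0.96), KRTAP2-3 (−1.40), the mitochondrial tRNA gene MT-TS2 (−0.93) and HOXB8, HOXB4 and HOXB6 completed the 12. KRTAP2-3 belongs to a family of near-identical genes, and polyA libraries are not made for tRNA, so both levels are uncertain.

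**Figure D2:**
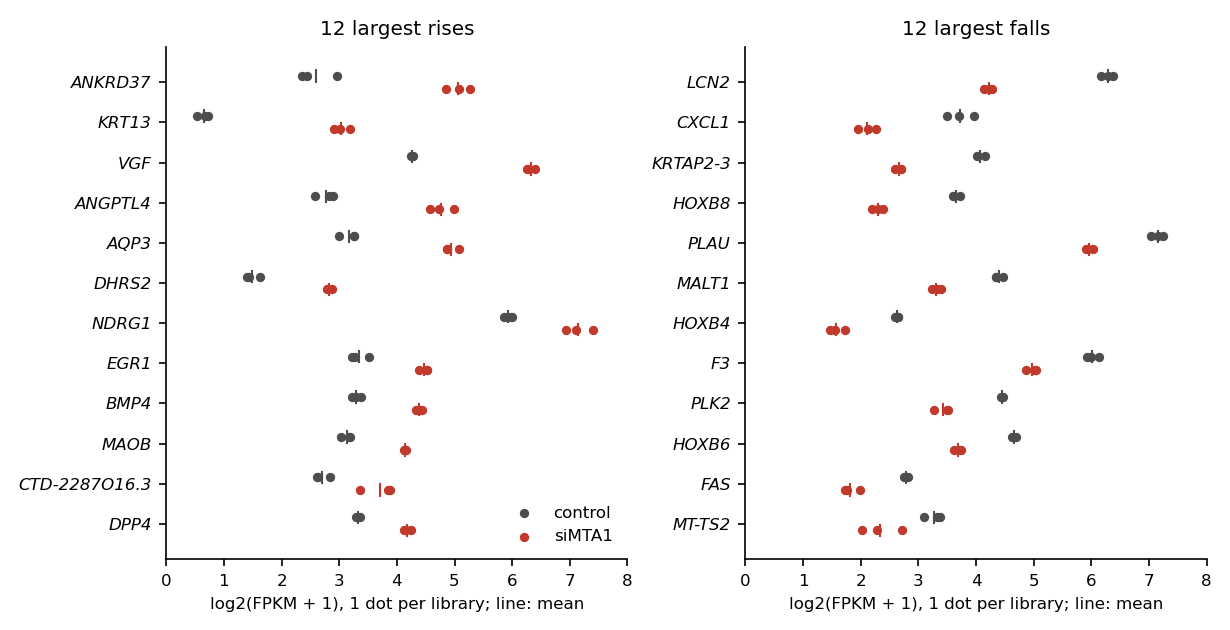
Level of the 12 genes with the largest rises and the 12 with the largest falls as log2(FPKM + 1), with a dot for each of the 3 control and 3 siMTA1 libraries and a line at each group mean. For each of the 24 genes the 3 values of a group lie on one side of the other group's, and log2 fold changes run from −2.07 for LCN2 to 2.48 for ANKRD37.

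HOXB genes code for homeodomain transcription factors that set position along the body axis, and 7 of the 8 tested members of this cluster fell with siMTA1. The cluster was singled out after its values were seen. HOXB8 was at 11.5 ± 0.55 FPKM in control and 3.90 ± 0.32 FPKM with siMTA1 (SD, n = 3, log2 fold change −1.35, adjusted p = 4.99e-06), HOXB4 at 5.20 ± 0.12 and 1.99 ± 0.28 FPKM, and HOXB6 at 24.2 ± 0.70 and 11.9 ± 0.52 FPKM. HOXB13 was the member that did not pass, with a log2 fold change of −0.19 (adjusted p = 0.0857). The 8 tested genes lie on chromosome 17 between 48548870 and 48729178 (GRCh38), and their median log2 fold change was −0.71. HOXB3 and HOXB7 are annotated across other HOXB genes on the same strand, so reads could have been shared among them.

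**Figure D3:**
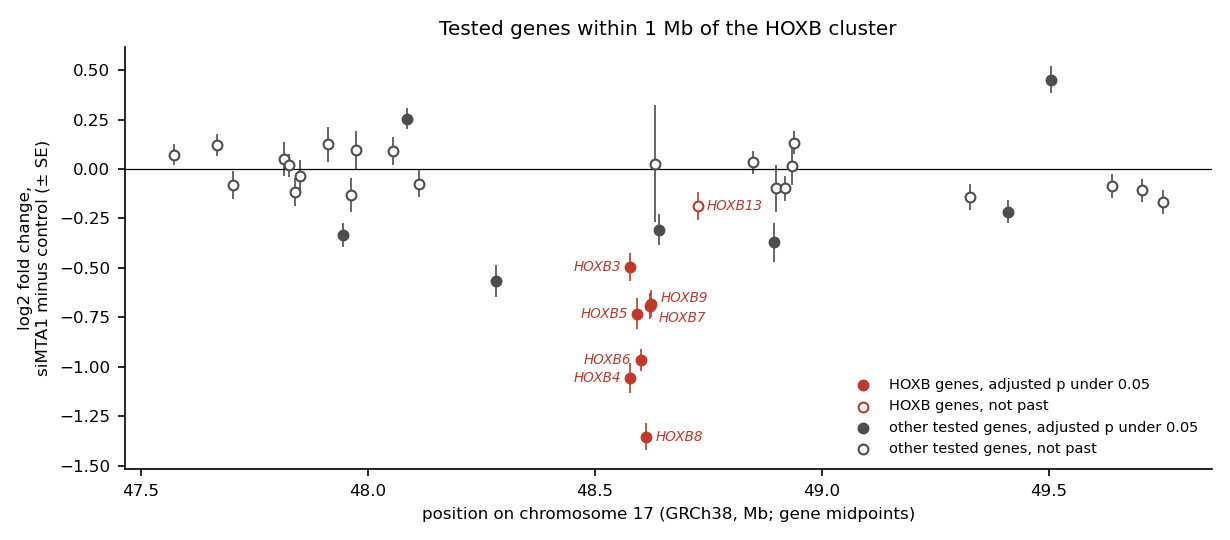
Log2 fold change (siMTA1 minus control, with standard errors) of every tested gene within 1 Mb of the HOXB cluster against its midpoint on chromosome 17 in Mb (GRCh38), with HOXB genes in red and filled points for adjusted p under 0.05. The 8 HOXB genes have a median of −0.71 and the 29 other genes a median of −0.07.

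Genes of the hypoxia response and of glycolysis rose: 17 of 33 tested members were higher and 0 lower (22 and 0 when adjusted over the list alone), with a median log2 fold change of 0.24. The list passed camera (adjusted p = 1.25e-16) and fry (adjusted p = 0.00713), but not camera with an estimated correlation (adjusted p = 0.163). Besides ANKRD37 and ANGPTL4, NDRG1 was at 59.9 ± 3.17 FPKM in control and 141.9 ± 23.1 FPKM with siMTA1, and the glycolytic enzyme gene ENO2 at 17.96 ± 0.95 and 28.5 ± 1.47 FPKM (SD, n = 3). Nuclear genes of oxidative phosphorylation moved down, with 16 of 45 lower and 0 higher (18 and 0 adjusted over the list alone). These genes had a median of −0.12, and −0.16 to −0.07 over all settings (adjusted p = 0.00126, but adjusted p = 0.146 with an estimated correlation). Among them NDUFS8, of complex I, was at 85.0 ± 2.58 and 66.8 ± 5.12 FPKM, and ATP5F1, of the ATP synthase, at 62.3 ± 2.36 and 49.8 ± 2.45 FPKM. Of the 15 mitochondrially encoded genes, 4 were lower and 1 higher (6 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.157), although it did under quantile normalization (adjusted p = 0.00325) and without control library 1 (adjusted p = 0.0302). MT-ND3 was at 3574.6 ± 206 FPKM in control and 2595.5 ± 97.9 FPKM with siMTA1. Genes of the mitochondrial genome made up 19.9% to 22.2% of the FPKM sum of a library.

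Mitotic genes were higher as a group. Of 52 genes of mitosis, spindle and cytokinesis, 29 were higher and 0 lower (39 and 0 adjusted over the list alone), with a median log2 fold change of 0.28. The camera adjusted p was 4.89e-22 and the fry adjusted p 0.00311, but the camera call ended with an estimated correlation (adjusted p = 0.0684). KIFC1, a spindle motor gene, was at 17.2 ± 0.99 FPKM in control and 25.4 ± 1.25 FPKM with siMTA1, and INCENP and AURKB, of the chromosomal passenger complex, had log2 fold changes of 0.56 and 0.42. Among 44 DNA replication genes, 9 were higher and 0 lower (13 and 0 adjusted over the list alone). That share is near the 18.2% of all 12141 tested genes that passed, of which 744 were higher and 1463 lower. The median of the 44 genes was 0.09, and 0.09 to 0.15 over all settings (adjusted p = 5.29e-08, but adjusted p = 0.0684 with an estimated correlation). The ribonucleotide reductase gene RRM1 (log2 fold change 0.29) and the replication licensing gene CDC6 (0.31) were examples.

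Targets of p53 fell, with 20 of 28 lower and 0 higher (25 and 0 adjusted over the list alone) and a median log2 fold change of −0.33. This was the list whose call also held with an estimated correlation (camera adjusted p = 2.46e-11, and 0.0313 with the estimate). CDKN1A, the cell cycle inhibitor p21, was at 154.4 ± 16.1 FPKM in control and 87.7 ± 2.88 FPKM with siMTA1 (SD, n = 3, log2 fold change −0.80, adjusted p = 0.000239). GDF15, a secreted stress cytokine, was at 401.1 ± 16.1 and 271.6 ± 13.8 FPKM, and TP53I3 at 7.96 ± 0.07 and 4.47 ± 0.57 FPKM.

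Immediate early genes and AP-1 components were higher in 11 of 23 members and lower in 1 (14 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.93e-08, but adjusted p = 0.163 with an estimated correlation). EGR1 was at 9.17 ± 1.13 FPKM in control and 21.3 ± 1.20 FPKM with siMTA1. DUSP6 and SPRY4, feedback inhibitors of ERK signalling, had log2 fold changes of 0.51 and 0.57. NF-kB targets and inflammatory genes were lower in 9 of 12 and higher in 0 (the same counts adjusted over the list alone), with a median of −0.30 (adjusted p = 0.000191, but adjusted p = 0.163 with an estimated correlation). NFKBIA, the inhibitor that NF-kB itself induces, was at 48.6 ± 0.90 and 31.7 ± 2.50 FPKM, and BIRC3 at 9.76 ± 1.65 and 5.56 ± 0.22 FPKM. The interferon response list went both ways, with 6 of 28 higher and 10 lower (7 and 15 adjusted over the list alone), and did not pass (adjusted p = 0.281). Of its members IFIT2 had a log2 fold change of −0.72 and OASL of 0.56.

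Heat shock genes were lower in 7 of 15 and higher in 0 (9 and 0 adjusted over the list alone), with a median of −0.24 (adjusted p = 0.00126, but adjusted p = 0.0847 with an estimated correlation). HSPA8, the constitutive HSP70, was at 670.65 ± 10.96 FPKM in control and 508.3 ± 11.3 FPKM with siMTA1. Genes of ATF4 and the unfolded protein response were higher in 6 of 32 and lower in 0 (the same adjusted over the list alone). That share is near the 18.2% of all 12141 tested genes that passed, of which 744 were higher and 1463 lower. The 32 genes of the list had a median of 0.09, and 0.07 to 0.14 over all settings (adjusted p = 0.000471, but adjusted p = 0.0684 with an estimated correlation). They included DDIT4 (log2 fold change 0.39), which the hypoxia list also holds, the asparagine synthetase gene ASNS (0.29) and the chaperone gene HYOU1 (0.43). Ribosome biogenesis factors were lower in 13 of 36 and higher in 0 (14 and 0 adjusted over the list alone), RRS1 among them at −0.33. Their median was −0.12, and −0.14 to −0.06 over all settings (adjusted p = 0.00205, but adjusted p = 0.219 with an estimated correlation). Ribosomal proteins of the cytosol had a median of −0.01 with 2 of 77 lower and 0 higher, 0 in both directions when adjusted over the list alone, and 5 lower and 3 higher at an unadjusted limma p under 0.05 (list adjusted p = 0.322). The camera direction of this list was up, against the sign of its median. Of 33 genes of cholesterol and fatty acid synthesis, 3 were lower and 0 higher (2 and 0 adjusted over the list alone). The sterol oxidase gene MSMO1 was among them at −0.59, but its call ended with no filter on low values (adjusted p = 0.101). This list did not pass (adjusted p = 0.319), but did with no filter on low values (adjusted p = 0.0431) and without siMTA1 library 3 (adjusted p = 0.00207). Autophagy and lysosome genes were higher in 3 of 25 and lower in 0 (2 and 0 adjusted over the list alone, list adjusted p = 0.338), with a median of −0.05 against a camera direction of up. The cathepsin gene CTSB was at 92.2 ± 5.64 and 118.9 ± 11.6 FPKM.

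Markers of epithelial junctions and keratins went both ways, with 3 of 29 higher and 4 lower (5 and 5 adjusted over the list alone). The list did not pass (adjusted p = 0.338), with a median of 0.01 and a mean of −0.01. The 2 members with the smallest adjusted p, which the rule names, were both higher. CDH1, or E-cadherin, was at 28.6 ± 0.58 FPKM in control and 34.6 ± 0.80 FPKM with siMTA1, and OVOL1 had a log2 fold change of 0.35. In the mesenchymal list, 6 of 19 were higher and 3 lower (7 and 3 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0168). Its call ended with an estimated correlation (adjusted p = 0.393), with fry (adjusted p = 0.111) and without control library 1 (adjusted p = 0.0835), where the median was 0.03. With no filter on low values the median was 0.00, and without control library 3 it was 0.21. SPARC, a matrix protein gene, was at 5.92 ± 0.16 and 10.8 ± 0.20 FPKM, fibronectin (FN1) at 1.16 ± 0.13 and 2.11 ± 0.21 FPKM, and thrombospondin (THBS1) at 3.45 ± 0.20 and 1.84 ± 0.12 FPKM. Among Wnt targets, 4 of 14 were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.00642, but adjusted p = 0.234 with an estimated correlation). That call also ended, and the median became −0.00, where a mean of 5 FPKM was required (adjusted p = 0.118). BMP4 was at 8.80 ± 0.53 and 19.98 ± 0.77 FPKM and SOX4 at 16.9 ± 0.28 and 28.02 ± 0.55 FPKM. The lower member was CCND1, at 239.4 ± 4.70 FPKM in control and 199.4 ± 6.79 FPKM with siMTA1. Its log2 fold change was −0.26 (adjusted p = 0.0105), and its call ended without control library 2 (adjusted p = 0.0547).

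Splicing factors, of interest because the title names splicing, were higher in 6 of 57 and lower in 1 (the same adjusted over the list alone). Of all 12141 tested genes 18.2% passed, a larger share than in this list, with 744 higher and 1463 lower. Over all tested genes the median was −0.05, and the list had a median of 0.04 (adjusted p = 0.00750, but adjusted p = 0.0847 with an estimated correlation). That median was 0.08 under upper-quartile scaling and, among alternatives chosen after the data were seen, 0.02 with the length and GC trend removed and 0.09 with median centring. The kinase gene CLK1 was at 14.4 ± 0.93 FPKM in control and 19.1 ± 1.28 FPKM with siMTA1, SRSF4 at 112.3 ± 8.49 and 140.1 ± 4.77 FPKM, and MBNL2 at 14.3 ± 0.78 and 10.9 ± 0.75 FPKM. Of 6 tested neuronal genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.0151, but adjusted p = 0.208 with an estimated correlation), and VGF changed most. The neuronal median moved to 0.01 with no filter on low values and to 0.31 where a mean of 0.1 FPKM was required. Of 18 genes found from the list of replication-dependent histones, 6 reached a mean of 1 FPKM in these polyA-selected libraries and were tested. Of these 6 histone genes, 1 was higher and 1 lower (1 and 2 adjusted over the list alone, list adjusted p = 0.459). Their median was −0.00 and their mean 0.04. The higher gene was H1F0, at 463.1 ± 32.6 and 617.3 ± 25.7 FPKM, a linker histone that the list holds although it is also made outside S phase and is not replication-dependent. Its call ended with no filter on low values (adjusted p = 0.0524). Most markers of other cell types were low. No haematopoietic marker reached a mean of 1 FPKM, while 2 fibroblast, 2 endothelial, 2 embryonic kidney or neuroblast and 1 hepatocyte marker did. Of these 0 passed in limma over all genes, but 2 fibroblast markers, COL1A1 and FBLN1, and 1 endothelial marker, ESAM, were higher both at an unadjusted p under 0.05 and adjusted over the list alone. COL1A1 belongs to the mesenchymal list too. The group means of these 3 genes stayed under 3 FPKM. The other tested endothelial marker, EGFL7, was higher in level, at 13.83 ± 0.53 FPKM in control and 14.07 ± 0.54 FPKM with siMTA1. All 4 were singled out after their values were seen. Of 3 tested intestinal differentiation genes 0 passed (1 higher adjusted over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05), and of 3 tested germline genes 1 was lower, also when adjusted over the list alone.

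**Figure D4:**
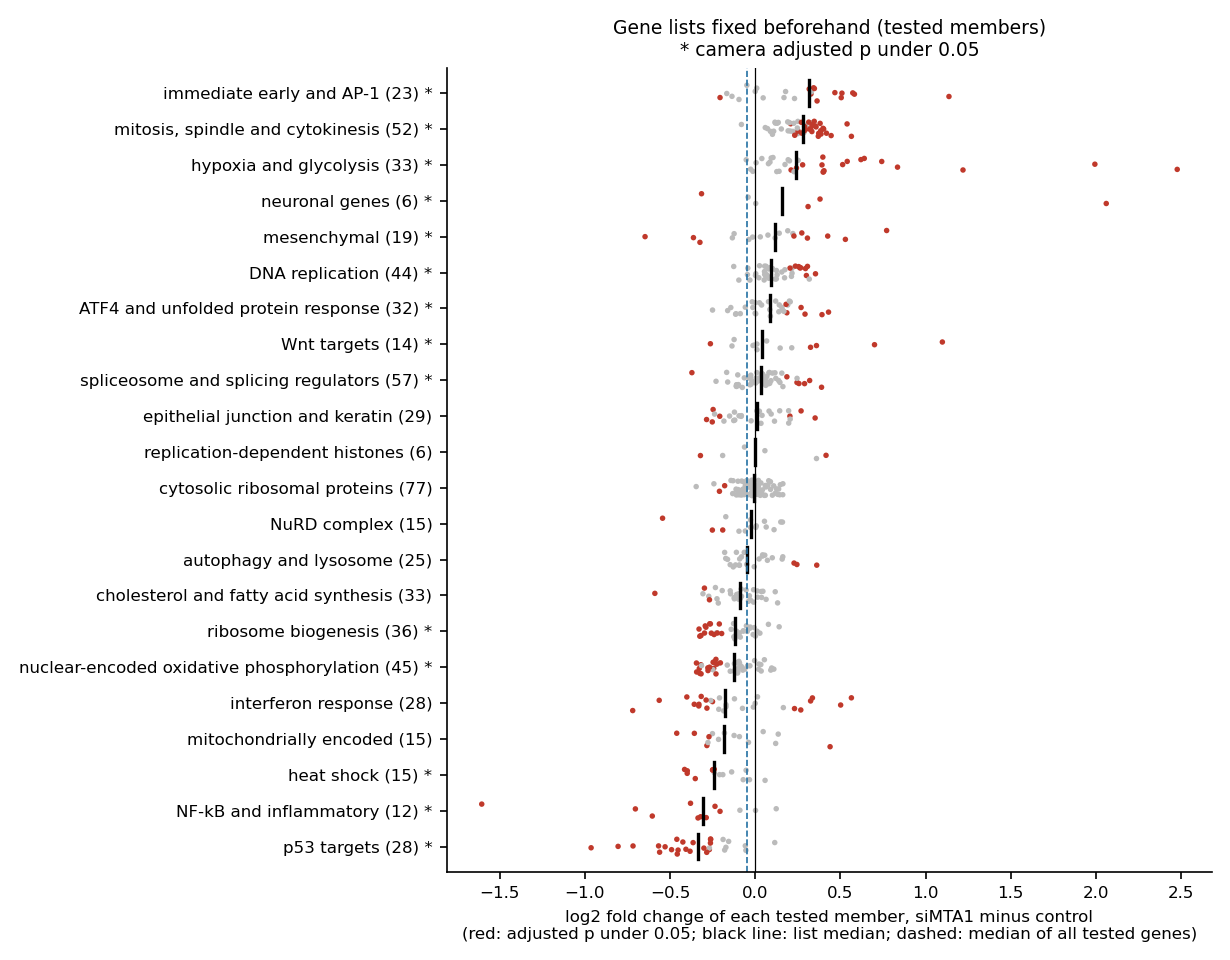
Log2 fold change (siMTA1 minus control) of each tested member of the 22 gene lists with at least 5 tested members, red where the adjusted p is under 0.05, with the list median as a black line, the median of all tested genes at −0.05 as a dashed line, the number of members in brackets and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Immediate early, mitotic and hypoxia genes have the highest medians, 0.32, 0.28 and 0.24, and p53 targets the lowest, −0.33.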

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

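The removal of a length and GC trend, the omission of mitochondrial genes and median centring were chosen only after the data were seen, and the other settings before the data were examined. The MTA1 level differed by −0.586 to −0.490 on the log2 scale over all alternatives run and stayed past the threshold in each. Over the genes named, 1996 results under alternatives kept their side of the threshold, 100 lost the call and 8 gained it. A change of sign counted as a reversal only where the gene passed in the main test or the alternative, and 0 such reversals occurred. Genes that passed in neither could change sign unseen. Over the lists, 506 results kept their side of the threshold, 16 lost the call and 4 gained it. The direction followed for lists was that of the set test, so the sign of a median could differ. The NuRD median, for example, ran from −0.05 to 0.03.

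Genes changed, 2207 of 12141 in the main test, numbered 676 with no filter on low values (297 higher, 379 lower), where 33126 genes entered the adjustment, 4049 with array weights (1434 higher, 2615 lower) and 3119 with the length and GC trend removed. Calls that ended with no filter included MT-ND3 (adjusted p = 0.111), CTSB (0.0914), SRSF4 (0.0713), MT-TS2 (0.0665), HYOU1 (0.0586) and NDUFS8 (0.0542). Quantile normalization gave 1011 higher and 895 lower, upper-quartile scaling 1000 and 939, and median centring 1128 and 802, so the majority of lower genes (1463 of 2207) did not hold under these. The median of all tested genes moved with these scalings from −0.05 to between −0.01 and 0.01, less than 0.1. With a pseudocount of 0.1, 46 genes changed at least 2-fold in place of 23, since a smaller pseudocount widens the folds of low genes. Leaving out a library gave 1046 (without control library 2) to 1773 changed genes, 391 to 633 of them higher and 642 to 1191 lower, and 1066 without siMTA1 library 2. Fewer libraries were then tested, so lower counts follow in part from the smaller number. NuRD subunits past the threshold numbered 1 with no filter or quantile normalization, 5 with array weights or the trend removed, and 1 to 2 with a library left out. Gene lists changed, 14 in the main test, numbered 1 with an estimated correlation in camera, 13 with fry, and 12 to 16 in the other settings. With fry the mesenchymal list alone lost its call. The estimated correlation was −0.02 for heat shock, −0.03 for ATF4 and the unfolded protein response and −0.004 for splicing factors. These values lie below the preset 0.01, so a larger correlation between genes is not why these calls ended. Estimates for the other lists that lost the call lay above the preset, from 0.016 for DNA replication to 0.50 for hypoxia and glycolysis. Whether the size of the estimate or another feature of this setting ended those calls was not tested. Where no cause is given here, the cause was not tested.

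With the replicate number as a block, 3031 genes changed (2039 lower) and 5 NuRD subunits passed, MTA2 and HDAC1 among them, which passed with array weights and the trend removed as well. The shared numbers were not treated as pairing, because the deviations of same-numbered libraries from their group means correlated at 0.33, 0.02 and 0.22 across genes. Libraries numbered 1 and 3 correlated best with the same number in the other group, and those numbered 2 with another number. The second principal component held 18.2% of the variance and followed replicate number in both groups. It stood at 8.9, −1.8 and −8.4 in control libraries 1, 2 and 3 and at 6.1, 2.2 and −7.0 in siMTA1 libraries 1, 2 and 3. A difference shared by same-numbered libraries therefore stays open.

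Count-based tests listed beforehand were not run, because the table holds FPKM. In the simulation, at this number of libraries, 50% of changes of 0.3 on the log2 scale were recovered. The share of small changes missed in the data was not tested.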

Other observations

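The gene lists of the next paragraph, the HOXB set, the test on the genes nearest to it and the test on DNA replication genes were chosen only after the results were seen, as was the trend removal.

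Actin cytoskeleton genes were higher with siMTA1 in 11 of 30 tested members and lower in 0, with a median log2 fold change of 0.15 (camera p = 6.82e-09, but p = 0.0834 with an estimated correlation). ACTB was at 521.7 ± 30.9 FPKM in control and 763.9 ± 36.5 FPKM with siMTA1 (SD, n = 3), ACTG1 at 1985.1 ± 45.0 and 3260.7 ± 301 FPKM, both with many pseudogene copies that could share reads in the alignment. Genes of MHC class I presentation and the immunoproteasome were lower in 8 of 15 and higher in 0, with a median of −0.26 (p = 0.000114, but p = 0.167 with an estimated correlation). The immunoproteasome gene PSMB9 (log2 fold change −0.76), the peptide transporter gene TAP1 (−0.50) and B2M, the light chain of class I molecules (−0.47), were among them. Mitochondrial ribosomal proteins were lower in 29 of 73 and higher in 0 (median −0.19), and subunits of the constitutive proteasome in 7 of 29 and higher in 0 (median −0.13). With an estimated correlation these gave p = 0.0295 and p = 0.0231, both with an adjusted p of 0.0885 over the lists of this kind. Aminoacyl-tRNA synthetases went both ways, with 4 of 20 higher and 3 lower.

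Genes of the hypoxia and glycolysis list lay 0.29 above the median of all tested genes on the log2 scale. A trend on transcript length and GC content was argued against as the cause, since the excess was 0.26 after its removal. Lower oxygen or a denser culture of the siMTA1 cells would also raise other targets of hypoxia-inducible factors, and 21 of these lay 0.14 above the median of all genes (camera p = 7.49e-05, but p = 0.156 with an estimated correlation), with 6 higher and AK4 lower. An effect of lower MTA1 on the same factors would look alike in this test, so that both the culture and MTA1 stay open as sources, and neither oxygen nor cell density is given in the sources used here.

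HOXB genes had a median log2 fold change of −0.71. A copy number difference over the whole window of 1 Mb on either side was argued against by the 29 other tested genes in it, whose median was −0.075 (95% bootstrap interval −0.11 to 0.03), with 2 higher and 5 lower. The intervals of this paragraph resampled genes, which share the same 6 libraries, so they leave out the spread between libraries. A copy number difference of a narrower region cannot be told apart, because of the nearest tested genes outside the cluster SKAP1 was lower (log2 fold change −0.57, adjusted p = 0.00272) and CALCOCO2 was not (0.03), and RP11-357H14.17 within the span was lower as well (−0.31, adjusted p = 0.0269). A fall of HOX genes in general as the whole cause was argued against by 12 tested HOXA, HOXC and HOXD genes, with a median of −0.14 (interval −0.24 to −0.04), but 3 of them (HOXA9, HOXA11 and HOXC9) were lower and 0 higher, so a smaller general fall stays open. A difference between selected lines, which the CrMTA1 in the titles leaves possible, and an effect of lower MTA1 stay open and were not tested.

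Mitotic genes lay 0.33 above and p53 targets 0.28 below the median of all genes, and after removal of the length and GC trend the values were 0.35 and −0.28, which argues against that trend. A larger share of cells in cycle, S phase included, would raise DNA replication genes as well. Their excess was 0.14 (95% bootstrap interval over genes 0.11 to 0.20), so their median was higher too. Whether they rose as far as the mark of 0.16 set for this explanation cannot be told apart because the interval spans it. The interval resampled genes, which share the same 6 libraries, so it leaves out the spread between libraries. Whether lower MTA1 itself changed these genes was not tested.

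The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2207 changed genes, 23 of them at least 2-fold, and 14 gene lists, and the highest of the other splits gave 0, 0 and 10. In each case 1 of the 10 splits gave a value as large. The other splits hold both groups on each side, so a group difference widens their spread and lowers their gene counts. Their 0 changed genes are therefore no measure of chance. They still passed 3 to 10 lists in camera at the preset correlation. A pass at that setting alone thus does not tie a list to siMTA1. How far these passes reflect the group difference left in the splits was not tested.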
